A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

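RNA of 3 yeast deletion strains (fun30D, htz1D and the double mutant fun30Dhtz1D) was compared with wild-type (WT) RNA on Agilent 2-colour arrays, 6 slides of 4 arrays each. Per the labels, cells grew in rich medium at 30 degrees to an optical density near 0.5, and cDNA was primed with oligo-dT from total RNA. Each strain had 3 biological replicates, each hybridised with the WT culture of the same number on 2 arrays with exchanged dyes, giving 18 arrays. Another 6 arrays held WT RNA in both dyes.

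The deposited spot intensities are the mean signal and the local median background of each channel as scanned, without normalization, extracted with Agilent Feature Extraction 9.5.3.1 per the file headers. The deposited log10 ratios of Cy5 over Cy3 were background-subtracted, detrended and dye-normalized by the same software, per the file headers. Per the submitters' processing notes, the authors used Feature Extraction and limma. The 6256 probes were each printed 7 times, with 1 probe per gene, and 0 spots were saturated. Between 1.15 and 15.2% of spots per array were marked as outliers by the software and left out.

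Intensities of the 18 arrays were corrected with normexp (offset 50) and loess within each array in limma 3.58.1 (R 4.3.3, and version 1.17.8 of the data.table package). Spots of a probe were averaged, ratios were turned to mutant over WT, and the dye swaps of a replicate were averaged, so that 9 values entered the model. A gene was tested if its signal was above background on at least 15 WT channels or on 5 channels of a mutant. This kept 6107 genes and left out 149. Group means were fitted with limma (lmFit and eBayes, residual df 6, prior df 4.14), and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were each mutant with WT, each pair of mutants, and the interaction (double mutant minus the sum of the single mutants on the log2 scale). The adjusted p of limma is not an exact test. The median signal and background stand with the data description of the results, and the number of arrays limits the precision.

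Replicate numbers pair the samples, since mutants of 1 number share a WT culture and slides. Deviations from the strain mean correlated by 0.17 to 0.733 over 9 pairs of the same number and by -0.629 to 0.222 over 18 pairs of different numbers. A replicate block was run as an alternative. Replicate 1 was scanned apart from replicates 2 and 3, and scan batch was run as a term, chosen after the data were seen.

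Gene lists were fixed before the data were examined, as were the comparisons, the rule for naming genes and most of the alternatives. Of 44 lists, 43 were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The intron list was not run, and windows in kilobases from telomeres were replaced by gene order, since no genome coordinates were used. Symbols and gene order came from a reference gene table, in which 5756 probe identifiers were found and 500 were not. The genes named were FUN30 and HTZ1, the 10 highest and 10 lowest ratios among genes called, changed the same way in 3 replicates and given a symbol other than the systematic name, and up to 4 members of each list with the lowest adjusted p. Between mutants and for the interaction, the 5 highest and 5 lowest were named. Genes of families with near-identical copies, listed by gene symbol, are marked as uncertain, and similar copies under other symbols are not.

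Alternatives were no background subtraction, normexp with offset 10, median centring, scaling between arrays, the deposited log10 ratios, no filter, a filter on all 18 arrays, each dye orientation alone, arrays not averaged, eBayes with trend and robust, separate fits, the replicate block, leaving out each replicate, a minimum change of 1.5-fold, and the 6 WT arrays as a group. The method was tested on simulated data with known changes in fun30D against WT, where 98.5% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1 were recovered, and 5.69% of 211 calls were false. Few genes were changed there, all by at least 0.5, and each gene had the same dye bias on every array, which dye swaps cancel. These shares therefore do not carry over to the many small changes called in the real fun30D arrays.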

Results

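RNA of 3 budding yeast deletion strains was compared with RNA of wild-type (WT) cells on 2-colour microarrays that held 1 probe per gene and 7 spots per probe. The strains lacked FUN30, which encodes an ATP-dependent chromatin remodelling enzyme of the Snf2 family, HTZ1, which encodes the histone variant H2A.Z, or both, and are written fun30D, htz1D and fun30Dhtz1D (the double mutant). Each strain had 3 biological replicates, and each replicate was hybridised on 2 arrays with the dyes exchanged. This gave 18 arrays of mutant against WT, and another 6 arrays carried WT RNA in both dyes. The median spot signal of the 18 arrays ranged from 3629 to 12160 in Cy3 and from 1572 to 13080 in Cy5, over median backgrounds of 67.5 to 79 and 73 to 89. Between 5929 and 6248 of the 6256 probes were above background per Cy3 channel, and the number of arrays limits the precision. Values given for a gene are mean log2(mutant/WT) ± SD of 3 replicates unless another comparison is named. On the 6 WT arrays both dyes held the same WT RNA, and their deposited ratios were used. There limma called 0 of 6107 genes different once the duplicates were turned as the mutant arrays were, and 250 genes had an unadjusted p under 0.05. With the same RNA in both dyes few calls are built in, and differences between cultures do not enter. The count is thus no rate of false calls for mutant against WT. Left unturned, the same arrays gave 1625 genes that differed between the dyes.

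The deleted genes were lowest where the labels place the deletions. FUN30 stood at -6.90 ± 0.58 in fun30D and -6.42 ± 0.66 in the double mutant (n = 3 each), against 0.092 ± 0.0024 in htz1D, where the adjusted p was 0.758 and the sign turned on the arrays with the mutant in Cy5. HTZ1 stood at -5.73 ± 0.90 in htz1D and -4.78 ± 1.15 in the double mutant, against -0.051 ± 0.050 in fun30D (adjusted p = 0.937). The FUN30 probe was above background on 2 of 6 arrays of fun30D and on 4 of 6 arrays of the double mutant. HTZ1 signal equal to 1.16, 1.52 and 3.83% of WT was left in the replicates of htz1D, and 1.45, 5.69 and 5.87% in those of the double mutant.

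The comparison of fun30D with WT asks which transcripts depend on Fun30, an enzyme that the series studies as a repressor of transcription at promoters. Without Fun30, COS12 had the highest ratio, single genes of the spore wall and the cell wall were among the highest, and single genes of arginine synthesis and of the mitochondrial genome were among the lowest. The fixed list of meiosis and sporulation genes was not called, with 14 of 44 genes higher and 7 lower (16 and 7 adjusted over the list alone), camera adjusted p = 0.0633 and adjusted p = 0.477 with an estimated correlation. Its member REC114, of meiotic recombination, fell by 0.64 on the log2 scale. YIR042C and YNR071C, genes near chromosome ends without a symbol of their own, stood at 1.25 ± 0.097 and 1.19 ± 0.077, between COS12 and GAS4. COS12 rose by 2.54 ± 0.088 (SD, n = 3; adjusted p = 3.67e-07) and COS1 by 0.93 ± 0.15; both belong to a family of membrane proteins with near-identical copies near chromosome ends, so their signals are uncertain, and COS12 was above background in WT on 4 of 6 arrays. The spore wall genes GAS4, a glucanosyltransferase, and DIT1, which makes the precursor of dityrosine, rose by 1.14 ± 0.12 and 1.13 ± 0.042, and GIP1, a meiosis-specific partner of the phosphatase Glc7, by 0.90 ± 0.066. PIR3, a cell wall glycoprotein, and YPS3, an aspartyl protease anchored at the cell surface, rose by 0.96 ± 0.34 and 0.87 ± 0.13. EFM6, which methylates a translation elongation factor, rose by 0.97 ± 0.14, and RNP1, an RNA-binding protein, by 0.89 ± 0.21. ATS1, which lies next to FUN30 on chromosome I, rose by 0.90 ± 0.13 here and by 0.96 ± 0.11 in the double mutant.

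Among the genes that fell in fun30D, SCP1, an actin-bundling protein, stood at -1.34 ± 0.059 (SD, n = 3; adjusted p = 1.41e-06) and HSP12, a small membrane-protecting stress protein, at -1.31 ± 0.29. ARG1, ARG7 and ARG3, enzymes of arginine synthesis, stood at -1.22 ± 0.33, -1.16 ± 0.14 and -1.12 ± 0.099, and BIG1, needed for cell wall beta-1,6-glucan, at -0.97 ± 0.086. The mitochondrially encoded ATP6, AI1 and COB stood at -1.06 ± 0.60, -0.96 ± 0.22 and -0.95 ± 0.69. Since cDNA was primed with oligo-dT, signal of mitochondrial DNA genes depends on how that primer binds their RNA, which was not tested. The same limit holds for every value and list call of mitochondrial DNA genes given below. Without replicate 1 the adjusted p was 0.0729 for ATP6, 0.179 for AI1 and 0.149 for COB, and without replicate 2 it was 0.0596 for AI1 and 0.225 for COB. On the arrays with the mutant in Cy3 alone it was 0.77 for AI1. COB was also past the threshold no longer with the replicate block (adjusted p = 0.0519), with the scan batch as a term (0.0653), and in 4 other settings.

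In all, 1561 of 6107 genes (25.6%) differed in fun30D, 786 higher and 775 lower, of which 5 were higher and 10 lower by at least 2-fold. Both dye orientations agreed little in this strain. Dye swaps correlated across genes by 0.143, 0.22 and -0.134 in its replicates, against 0.482 or more in every replicate of htz1D and the double mutant. Changes were small, and the count rested on the replicates: 268 genes differed without replicate 1, 756 without replicate 2 and 1132 without replicate 3. Replicate 1 was scanned as a batch apart from replicates 2 and 3, so that 268 is also the count within the later batch, and 1415 genes differed with the batch as a term; the earlier batch holds 1 replicate per strain and gives no value. Scaling the spread between arrays gave 2529 genes, contrasting with the 6 WT arrays on the deposited ratio scale, which changed both choices at once, gave 904 (the deposited ratios alone gave 1491), and a minimum change of 1.5-fold left 94.

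Several lists of genes near chromosome ends were called higher in fun30D. On the arrays with the mutant in Cy3 alone the COS list kept its call, and the call ended for the outermost 5 places (0.974), the seripauperin genes (0.535), places 6 to 10 (0.0652) and the aryl-alcohol dehydrogenase (AAD) and vitamin genes (0.0688). Helicase genes of Y' elements, another family of chromosome ends, were not called, with 0 of 8 genes called by limma in either direction (0 adjusted over the list alone) and a camera adjusted p of 0.174. Of 12 COS genes, 10 were higher and 0 lower (11 and 0 adjusted over the list alone), with a median of 0.23 and a camera adjusted p of 4.59e-07 (adjusted p = 0.17 with an estimated correlation). Of 30 genes of the seripauperin list, 19 were higher and 0 lower (27 and 0 adjusted over the list alone), among them TIR4 at 0.42 ± 0.044 and PAU10 at 0.35 ± 0.10. The list, called seripauperin genes throughout, holds PAU genes, small cell wall mannoproteins with near-identical copies. It also holds mannoprotein genes without the PAU symbol, such as TIR4 and DAN1. For the seripauperin genes camera gave adjusted p = 1.43e-08, and adjusted p = 0.332 with an estimated correlation. Of 140 genes in the outermost 5 places of chromosome ends, 53 were higher and 22 lower (64 and 25 adjusted over the list alone). For the outermost 5 places camera gave adjusted p = 0.000137, and adjusted p = 0.431 with an estimated correlation. Of 146 genes in places 6 to 10, 38 were higher and 12 lower (42 and 13 adjusted over the list alone), including MAL33, a maltose activator with similar copies, at 0.78 ± 0.20. For places 6 to 10 camera gave adjusted p = 0.00355, and adjusted p = 0.0936 with an estimated correlation. Places 11 to 15 had 24 higher and 25 lower of 147 genes (camera adjusted p = 0.878). The AAD and vitamin genes of chromosome ends had 3 of 13 higher (4 adjusted over the list alone), with SNZ3, of vitamin B6 synthesis, at 0.28 ± 0.071. For the AAD and vitamin genes camera gave adjusted p = 0.00226, and adjusted p = 0.17 with an estimated correlation.

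In fun30D, of 35 glucose-repressed genes, 13 were higher and 2 lower (16 and 2 adjusted over the list alone), with REG2, a phosphatase subunit, at 0.55 ± 0.090 and FOX2, of peroxisomal fatty acid oxidation, at 0.50 ± 0.12. For the glucose-repressed genes camera gave adjusted p = 0.00086, and adjusted p = 0.332 with an estimated correlation. Of 37 nuclear genes of oxidative phosphorylation, 16 were lower and 0 higher (18 and 0 adjusted over the list alone), with the ATP synthase subunits ATP18 at -0.78 ± 0.012 and ATP16 at -0.51 ± 0.058. For oxidative phosphorylation camera gave adjusted p = 5.45e-06, and adjusted p = 0.332 with an estimated correlation. Of 8 mitochondrial DNA genes, 4 were lower (5 adjusted over the list alone). For the mitochondrial DNA genes camera gave adjusted p = 0.0331, 0.0841 without replicate 1, and adjusted p = 0.402 with an estimated correlation. Of 54 targets of Gcn4, the activator of amino acid synthesis, 15 were lower and 2 higher (19 and 2 adjusted over the list alone), with LYS1 at -0.50 ± 0.086. For the Gcn4 targets camera gave adjusted p = 0.000114, and adjusted p = 0.332 with an estimated correlation. Of 41 G1/S genes, 17 were lower and 0 higher (20 and 0 adjusted over the list alone), with the ribonucleotide reductase gene RNR1 at -0.48 ± 0.093 and the S-phase cyclin CLB6 at -0.44 ± 0.098. For the G1/S genes camera gave adjusted p = 4.36e-05, and adjusted p = 0.174 with an estimated correlation. Of 25 G2/M genes, 7 were lower and 0 higher (9 and 0 adjusted over the list alone), with the transcription factor SWI5 at -0.25 ± 0.068. For the G2/M genes camera gave adjusted p = 0.000897, and adjusted p = 0.275 with an estimated correlation.

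Cell wall integrity genes had 10 of 25 higher and 0 lower in fun30D (11 and 0 adjusted over the list alone), with NCW2 at 0.86 ± 0.095 and the protease YPS1 at 0.52 ± 0.16. For the cell wall genes camera gave adjusted p = 0.00485, and adjusted p = 0.332 with an estimated correlation. The proteasome had 5 of 34 higher and 0 lower (5 and 0 adjusted over the list alone), a call that ended without replicate 1 (0.0835) and with median centring (0.0958). For the proteasome camera gave adjusted p = 0.00711, and adjusted p = 0.431 with an estimated correlation. Subunits of other remodellers had 6 of 21 lower and 1 higher (6 and 1 adjusted over the list alone), with ITC1 of the Isw2 complex at -0.31 ± 0.071 and SWI1 of SWI/SNF at -0.24 ± 0.043. For the other remodellers camera gave adjusted p = 0.00256, and adjusted p = 0.246 with an estimated correlation. Genes next to FUN30 or HTZ1 had 6 of 12 higher and 0 lower (7 and 0 adjusted over the list alone). For these neighbours camera gave adjusted p = 0.0055, and adjusted p = 0.275 with an estimated correlation. Of 138 ribosomal protein genes, 11 were lower and 0 higher (0 and 0 adjusted over the list alone), and the direction turned on the arrays with the mutant in Cy5 (2.88e-11 upward). For the ribosomal protein genes camera gave adjusted p = 0.000137 downward, and adjusted p = 0.578 with an estimated correlation. The other 27 lists were not called (camera adjusted p from 0.0559, phosphate genes, to 0.959, the SWR1 complex). With the replicate block, run at the preset correlation only, the phosphate list was called lower (0.0469). Without the block camera gave it adjusted p = 0.332 with an estimated correlation. With the arrays that carried the mutant in Cy3 alone, 4 of the 16 called lists stayed past the threshold. Besides the chromosome-end lists, the calls ended for glucose-repressed genes (0.135), oxidative phosphorylation (0.0652), mitochondrial DNA genes (0.204), Gcn4 targets (0.0652), G1/S genes (0.0688), G2/M genes (0.0962), cell wall integrity genes (0.216) and other remodellers (0.254). With those in Cy5 alone, 13 stayed, and the calls ended for the neighbours (0.154) and the proteasome (0.842). The mitochondrial DNA call also ended with scaling between arrays (0.0531), and the ribosomal protein call with arrays not averaged (0.0796).

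**Figure D1:**
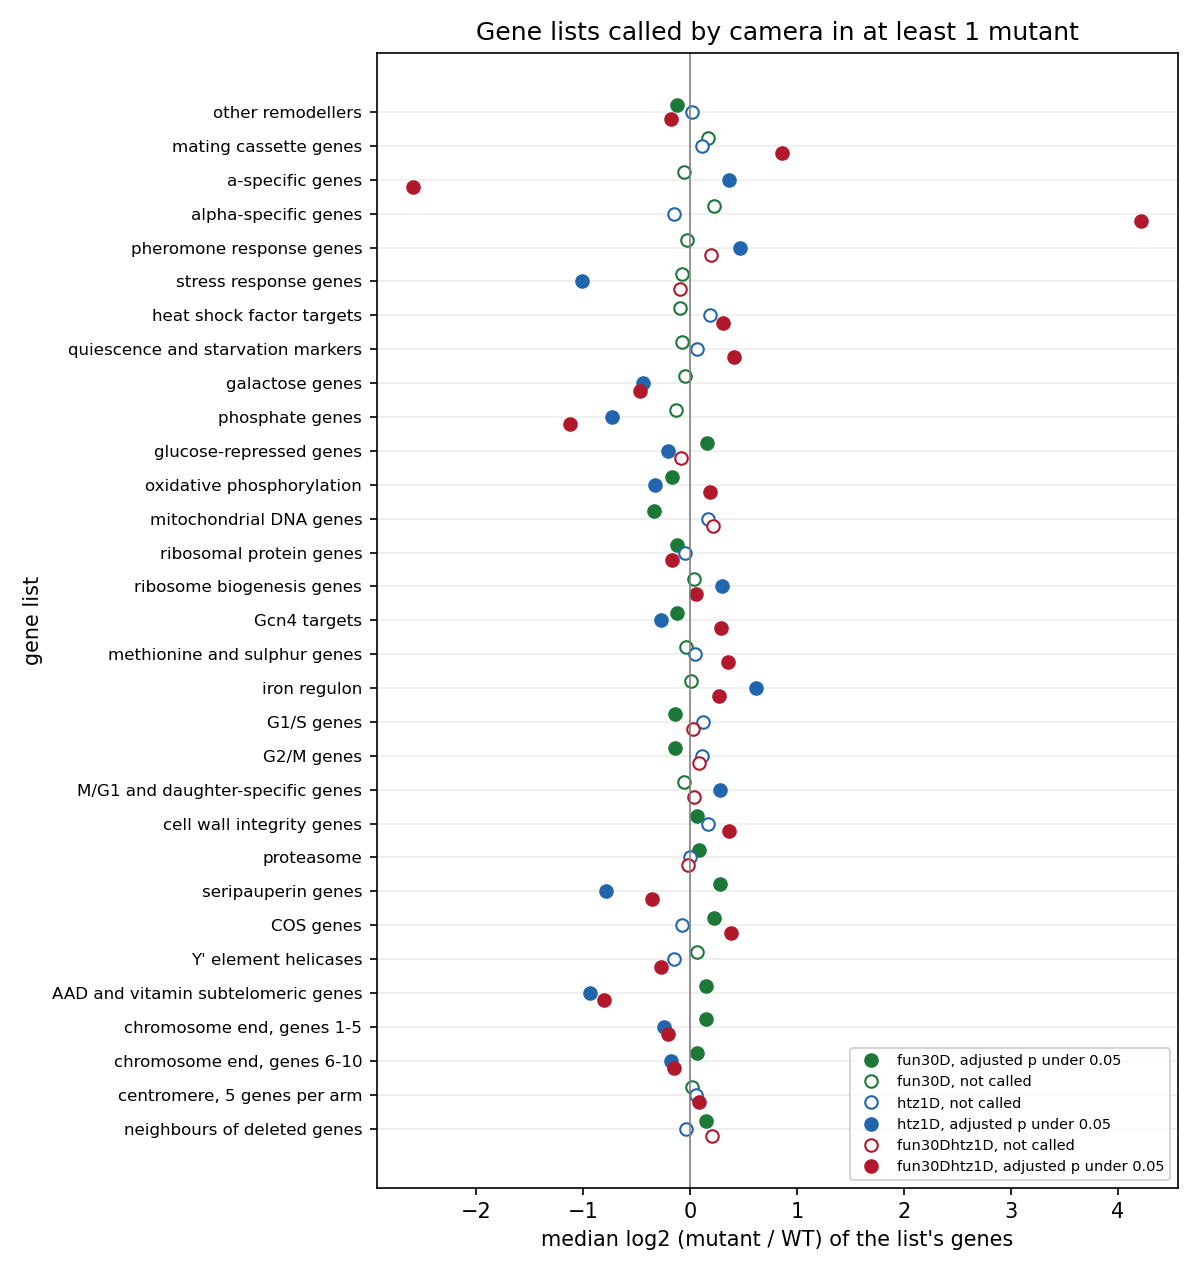
Median log2(mutant/WT) of each gene list that camera called in at least 1 mutant, with filled points for an adjusted p under 0.05 and open points otherwise. In fun30D the medians of the called lists were small, the stress response list of htz1D stood at -1.01, and the mating-type lists of the double mutant stood furthest out at -2.59 and 4.22; the ribosomal protein list turned direction in fun30D with the mutant in Cy5 and in the double mutant with that choice or with median centring.

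The comparison of htz1D with WT asks which transcripts depend on the histone variant H2A.Z. Without it, the iron regulon list was called higher, and the lists of stress response genes, of phosphate genes and of genes near chromosome ends were called lower. With an estimated correlation the phosphate list (adjusted p = 0.0377) and places 6 to 10 from chromosome ends (adjusted p = 0.0236) kept the call, and the iron regulon (adjusted p = 0.279), the stress response genes (adjusted p = 0.239) and the outermost 5 places (adjusted p = 0.279) lost it. FIT2 and FIT3, cell wall proteins that retain siderophore iron, rose by 1.68 ± 0.085 (SD, n = 3; adjusted p = 5.11e-09) and 1.64 ± 0.17, the siderophore transporters SIT1 and ARN1 by 1.62 ± 0.25 and 1.46 ± 0.13, the reductase gene FRE5 by 1.54 ± 0.42, and TIS11, which degrades mRNA under iron shortage, by 1.42 ± 0.28. The ferric reductase gene FRE1 had a ratio of 1.21 ± 1.04, with 2.41 in replicate 3 against 0.67 and 0.55 (adjusted p = 0.0401; 0.118 without replicate 1, 0.0651 with the scan batch as a term, and past the threshold no longer in 3 other settings). DAN1, a cell wall mannoprotein of anaerobic growth whose family has similar copies, rose by 2.36 ± 0.29 and was above background in WT on 4 of 6 arrays. PGU1, an endopolygalacturonase, rose by 1.62 ± 0.11 and MAL33 by 1.21 ± 0.20.

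The genes that fell most in htz1D included EGO4 at -3.16 ± 0.17 (SD, n = 3; adjusted p = 1.51e-09), the zinc cluster factor gene RDS1 at -3.08 ± 0.37, SOL4, of the pentose phosphate pathway, at -2.91 ± 0.14, and the mitochondrial MCO32 at -2.57 ± 0.17. AAD3 and COS10, members of families with similar copies at chromosome ends, stood at -2.81 ± 0.22 and -2.75 ± 0.15. CYC7, the second form of cytochrome c, stood at -2.59 ± 0.56, the glycogen synthase gene GSY1 at -2.55 ± 0.39 and ARG1 at -2.52 ± 0.53. In all, 3358 of 6107 genes (55%) differed, 1679 higher and 1679 lower. At least 2-fold, 29 were higher and 180 lower, and with a minimum of 1.5-fold the counts were 189 and 445. Loess centres each array, so the even split does not show that rises and falls balance, and the deposited ratios gave 1862 higher and 1495 lower. Fitted separately for each mutant, 2294 genes differed in htz1D, 1836 in fun30D and 3890 in the double mutant. Within the later scan batch, that is without replicate 1, 2320 genes differed, and 3286 with the batch as a term.

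In htz1D, of 47 stress response genes, 38 were lower and 2 higher (38 and 2 adjusted over the list alone), with a median of -1.01 and a camera adjusted p of 5.53e-14 (adjusted p = 0.239 with an estimated correlation); MSC1 stood at -1.72 ± 0.11, DCS2, an inhibitor of mRNA decapping, at -1.66 ± 0.12 and GAD1, a glutamate decarboxylase, at -1.82 ± 0.13. Of 18 phosphate genes, 15 were lower and 0 higher (15 and 0 adjusted over the list alone), with the acid phosphatase PHO5 at -2.46 ± 0.19 and the regulator SPL2 at -0.74 ± 0.11. For the phosphate genes camera gave adjusted p = 4.41e-07, and adjusted p = 0.0377 with an estimated correlation. Of 11 galactose genes, 8 were lower and 2 higher (8 and 2 adjusted over the list alone), among them the activator gene GAL4 at -1.04 ± 0.20. For the galactose genes camera gave adjusted p = 0.0215, and adjusted p = 0.283 with an estimated correlation. Of 37 oxidative phosphorylation genes, 26 were lower and 0 higher (28 and 0 adjusted over the list alone), with CYC1, the main cytochrome c, at -0.91 ± 0.21. For oxidative phosphorylation camera gave adjusted p = 7.14e-07, and adjusted p = 0.264 with an estimated correlation. Glucose-repressed genes had 19 of 35 lower and 6 higher (20 and 6 adjusted over the list alone), with the hexose transporter HXT4 at -1.49 ± 0.25. For the glucose-repressed genes camera gave adjusted p = 0.0153, and adjusted p = 0.413 with an estimated correlation. Gcn4 targets had 32 of 54 lower and 5 higher (33 and 6 adjusted over the list alone), with ARG3 at -1.75 ± 0.36 and HIS5 at -0.92 ± 0.15. For the Gcn4 targets camera gave adjusted p = 7.04e-05, and adjusted p = 0.279 with an estimated correlation.

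In htz1D, of 29 genes of the iron regulon, 23 were higher and 2 lower (24 and 2 adjusted over the list alone), with a median of 0.61 and a camera adjusted p of 2.99e-07 (adjusted p = 0.279 with an estimated correlation). Of 118 ribosome biogenesis genes, 97 were higher and 1 lower (99 and 1 adjusted over the list alone), with IPI1, of pre-rRNA processing, at 0.82 ± 0.12 and NOP15 at 0.53 ± 0.018. For ribosome biogenesis camera gave adjusted p = 5.53e-14, and adjusted p = 0.095 with an estimated correlation. Of 22 pheromone response genes, 18 were higher and 1 lower (18 and 1 adjusted over the list alone), with FIG1 at 1.17 ± 0.088 and PRM1, of cell fusion, at 0.87 ± 0.033. For the pheromone response genes camera gave adjusted p = 2.28e-06, and adjusted p = 0.0306 with an estimated correlation. Of 7 a-specific genes, 4 were higher and 0 lower (5 and 0 adjusted over the list alone), with the pheromone genes MFA1 at 0.65 ± 0.40 and MFA2 at 0.50 ± 0.17. For the a-specific genes camera gave adjusted p = 0.0215, 0.0586 without replicate 2, and adjusted p = 0.279 with an estimated correlation. The alpha-specific list was not called, with 0 of 4 genes higher and 2 lower by limma (0 and 2 adjusted over the list alone) and a camera adjusted p of 0.225, and its member STE3, the a-factor receptor gene, stood at -1.52 ± 0.24. M/G1 and daughter-specific genes had 14 of 25 higher and 0 lower (14 and 0 adjusted over the list alone), with the G1 cyclin CLN3 at 0.40 ± 0.13. For the M/G1 genes camera gave adjusted p = 0.00373, and adjusted p = 0.237 with an estimated correlation.

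In htz1D, of 140 genes in the outermost 5 places, 85 were lower and 18 higher (87 and 20 adjusted over the list alone), with AIF1, a cell death factor, at -2.28 ± 0.095 and GEX2, a glutathione exchanger, at -1.99 ± 0.028. For the outermost 5 places camera gave adjusted p = 2.93e-08, and adjusted p = 0.279 with an estimated correlation. Of 146 genes in places 6 to 10, 73 were lower and 26 higher (75 and 28 adjusted over the list alone), with PHR1, the DNA photolyase, at -1.35 ± 0.032. For places 6 to 10 camera gave adjusted p = 7.04e-05, and adjusted p = 0.0236 with an estimated correlation. Places 11 to 15 had 59 of 147 lower and 36 higher (camera adjusted p = 0.164), and places 16 to 25 had 106 of 302 lower and 62 higher (0.249). Of 30 seripauperin genes, 25 were lower and 2 higher (25 and 2 adjusted over the list alone), with PAU20 at -2.45 ± 0.26 while DAN1 rose. For the seripauperin genes camera gave adjusted p = 2.71e-08, and adjusted p = 0.279 with an estimated correlation. Of 13 AAD and vitamin genes, 10 were lower and 1 higher (10 and 1 adjusted over the list alone), with SNZ3 at -1.41 ± 0.16 and SNZ2 at -1.16 ± 0.068, both with similar copies. For the AAD and vitamin genes camera gave adjusted p = 4.98e-05, and adjusted p = 0.0377 with an estimated correlation. The other 28 lists had camera adjusted p from 0.0519 (cell wall integrity genes) to 0.842, and the SWR1 complex, which places H2A.Z in chromatin, was among them (0.538), although its ATPase gene SWR1 rose by 0.79 ± 0.16. On the arrays with the mutant in Cy5 alone, 3 of the 15 called lists lost the call: a-specific genes (0.136), glucose-repressed genes (0.132) and M/G1 genes (0.0576). The a-specific call also ended with arrays not averaged (0.0623).

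The comparison of the double mutant with WT asks what the loss of both factors does, and its RNA differed from that of the other strains in mating-type genes, in marker genes and along 1 chromosome. The alpha-specific genes MF(ALPHA)1 and MF(ALPHA)2, which encode alpha-factor, rose by 6.46 ± 0.11 (SD, n = 3; adjusted p = 1.68e-13) and 5.35 ± 0.49, the a-factor receptor gene STE3 by 3.09 ± 0.23 and the agglutinin gene SAG1 by 2.52 ± 0.0063. The a-specific genes STE2, the alpha-factor receptor, STE6, the a-factor exporter, BAR1, a protease of alpha-factor, and MFA1 and MFA2, which encode a-factor, stood at -2.79 ± 0.082, -2.62 ± 0.12, -2.55 ± 0.074, -2.59 ± 0.094 and -2.68 ± 0.10. Single genes known to be transcribed in haploid cells also fell, although no list of such genes alone was fixed. The fixed list of pheromone response genes mixes Ste12 targets with haploid-specific genes. It had 11 of 22 genes higher and 9 lower and was not called (camera adjusted p = 0.699). The mating-type endonuclease gene HO stood at -3.22 ± 0.16, the meiosis repressor RME1 at -2.27 ± 0.056, the G protein subunits STE18 and STE4 at -2.29 ± 0.15 and -2.17 ± 0.025, and the mating kinase FUS3 at -1.96 ± 0.12. Named after their values were seen, GPA1, NEJ1, FAR1 and STE5 stood at -2.10, -2.13, -1.89 and -1.85, and the meiotic gene IME4 at 2.43. Of these, GPA1 and FAR1 are members of the pheromone response list, as are STE18, STE4 and FUS3.

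Marker genes also set the double mutant apart. MET17, of methionine synthesis and a common deletion marker of laboratory strains, stood at 8.08 ± 0.32 (SD, n = 3; adjusted p = 3.05e-12), and its probe was above background in WT on 4 of 6 arrays. LYS2, of lysine synthesis and another such marker, stood at -5.61 ± 0.093, with 1.96, 2.21 and 2.01% of the WT signal left in the 3 replicates. The same genes stood at 0.076 and -0.39 in fun30D and at -0.0024 and -0.61 in htz1D.

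**Figure D2:**
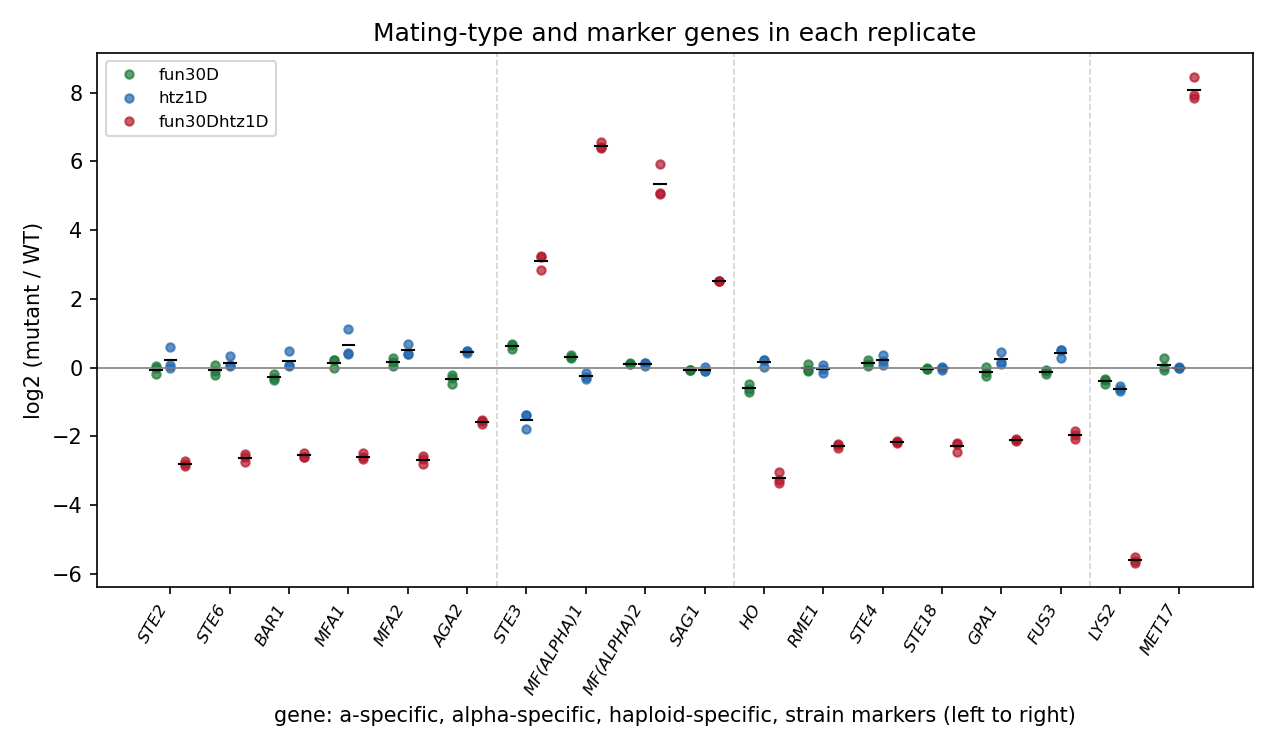
Log2(mutant/WT) of a-specific, alpha-specific, haploid-specific and marker genes, with 1 point per replicate and a bar at the mean of 3. In the double mutant MF(ALPHA)1 lay between 6.38 and 6.58, STE2 between -2.87 and -2.71 and MET17 between 7.86 and 8.45.

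Of 153 genes tested on chromosome III in the double mutant, 138 were higher and 6 lower, with a median of 0.68 (a ratio of 1.6) and replicate medians of 0.63, 0.66 and 0.68. The medians of the other 15 nuclear chromosomes lay between -0.14 and 0.018, and chromosome III stood at -0.0064 in fun30D and -0.026 in htz1D. Camera gave chromosome III an adjusted p of 6.75e-31, and 0.000211 with an estimated correlation. Without the mating and marker lists, the left arm had a median of 0.67 over 50 genes and the right arm 0.66 over 93. Along the chromosome in 8 runs of genes, the rise was lower at the right end, with medians of 0.43 and 0.21 in the last runs against 0.65 to 0.84 in the others. In htz1D the same last runs stood at -0.17 and -0.43. Of 6 mating cassette genes, which all lie on chromosome III and share sequence, 5 were higher and 1 lower (5 and 1 adjusted over the list alone), with MATALPHA1 at 0.94 ± 0.091; the one that fell, HMRA1, stood at -0.35 and is named after its value was seen. For the cassette genes camera gave adjusted p = 0.00538, and adjusted p = 0.264 with an estimated correlation.

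**Figure D3:**
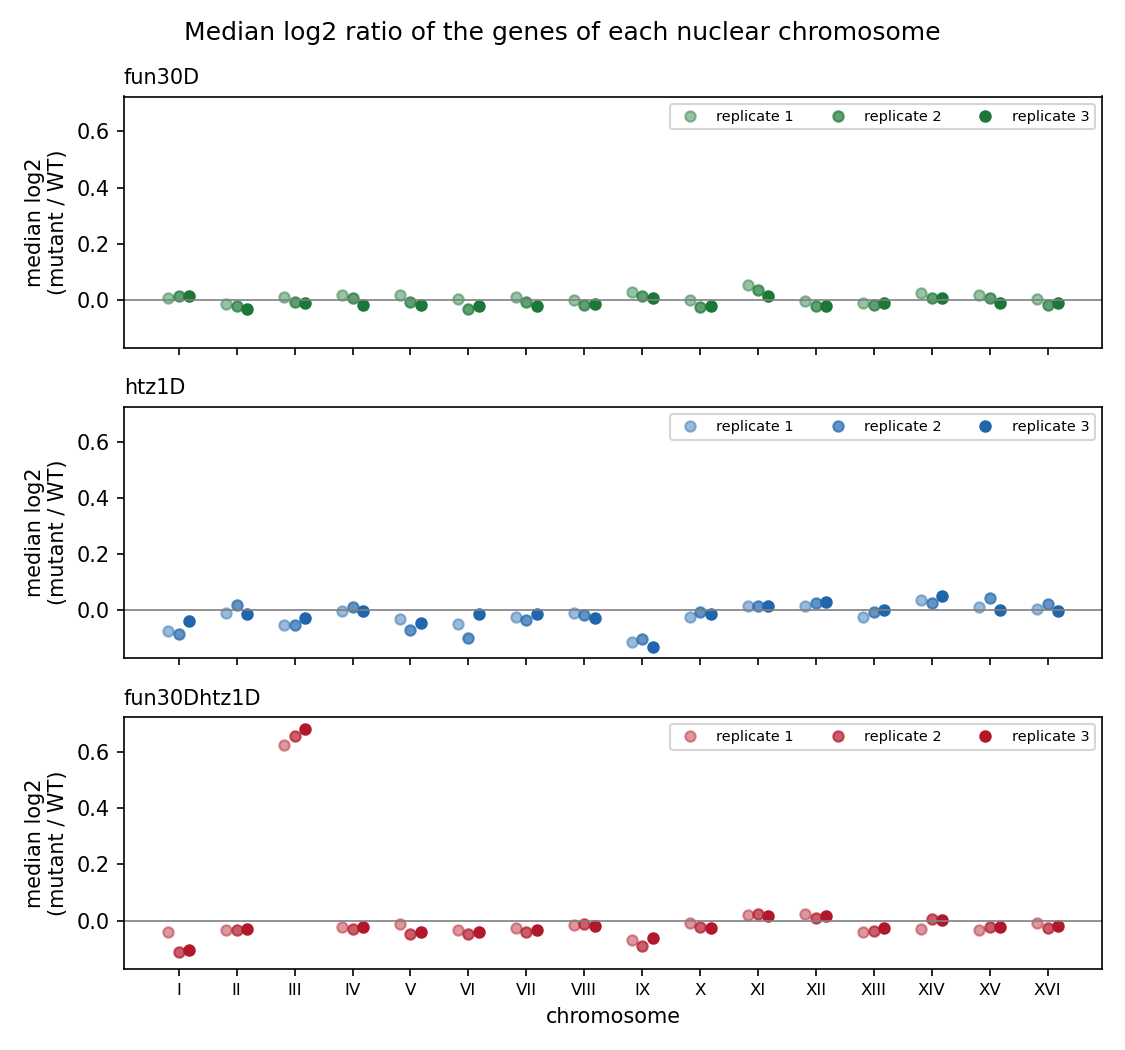
Median log2(mutant/WT) of the genes of each nuclear chromosome, with 1 point per replicate in fun30D, htz1D and the double mutant. In the double mutant chromosome III lay at 0.63 to 0.68 and every other median between -0.14 and 0.018 for the mean of the replicates.

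**Figure D4:**
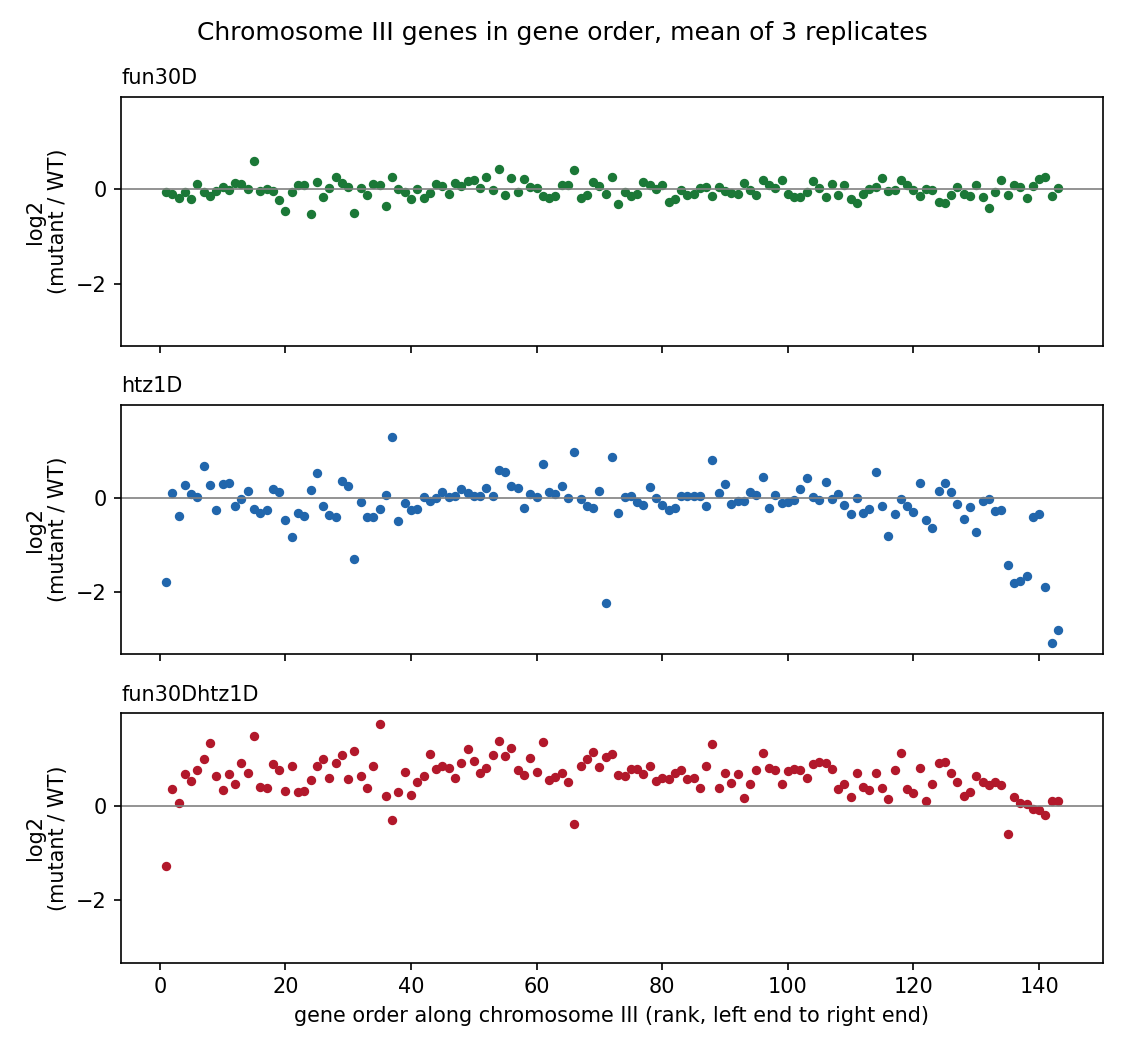
Log2(mutant/WT) of chromosome III genes in gene order, left end to right end, as the mean of 3 replicates and without the genes of the mating and marker lists. The medians of the double mutant were 0.67 on the left arm and 0.66 on the right arm, single genes such as GEX1 at -1.28 lay below 0, and the last 18 genes of the right end had a median of 0.21.

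Beyond these genes, the double mutant had its highest ratios in HPF1 and CSS1, cell wall proteins of similar sequence, at 3.38 ± 0.65 (SD, n = 3; adjusted p = 3.81e-07) and 3.29 ± 0.59, in HSP12 at 3.07 ± 0.66, in NCA3, of mitochondrial ATP synthase expression, at 2.70 ± 0.12, and in FIG1 at 2.61 ± 0.082. PHO12, an acid phosphatase with similar copies, stood at -2.72 ± 0.16 and PHO5 at -1.98 ± 0.052. In all, 3340 of 6107 genes (54.7%) differed, 1624 higher and 1716 lower, of which 80 and 91 by at least 2-fold and 580 by at least 1.5-fold. With the genes of chromosome III and of the mating, meiosis, methionine and marker lists left out, a choice made after the values were seen, 3097 genes differed. Within the later scan batch 2281 genes differed, and 3251 with the batch as a term.

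Gene groups of the double mutant have to be read beside its chromosome III median of 0.68 and its mating-type and marker genes, since no list can be separated from them. All 7 a-specific genes were lower and all 4 alpha-specific genes higher, also adjusted over the list alone (camera adjusted p = 9.36e-07 and 6.85e-06; adjusted p = 0.075 and 0.0607 with an estimated correlation). Of 18 phosphate genes, 17 were lower and 0 higher (18 and 0 adjusted over the list alone), with VTC4, of polyphosphate synthesis, at -1.28 ± 0.073. For the phosphate genes camera gave adjusted p = 2.05e-09, and adjusted p = 0.0566 with an estimated correlation. Of 11 galactose genes, 8 were lower and 1 higher (8 and 1 adjusted over the list alone), with GAL4 at -1.41 ± 0.10 and GAL1 at -1.16 ± 0.078. For the galactose genes camera gave adjusted p = 0.008, and adjusted p = 0.264 with an estimated correlation. Of 29 iron regulon genes, 16 were higher and 4 lower (16 and 4 adjusted over the list alone), with FRE5 at 1.24 ± 0.17. For the iron regulon camera gave adjusted p = 0.00538, and adjusted p = 0.487 with an estimated correlation. Of 54 Gcn4 targets, 29 were higher and 6 lower (31 and 6 adjusted over the list alone). The list holds the marker genes MET17 and LYS2 and the chromosome III genes ILV6 at 1.11 ± 0.30, HIS4 and THR4. For the Gcn4 targets camera gave adjusted p = 0.000721, and adjusted p = 0.356 with an estimated correlation. Of 25 methionine and sulphur genes, 16 were higher and 5 lower (16 and 5 adjusted over the list alone), with MET10 at 0.55 ± 0.066. The marker gene MET17 is a member of this list. For the methionine and sulphur genes camera gave adjusted p = 0.00766, and adjusted p = 0.426 with an estimated correlation. Of 25 cell wall integrity genes, 16 were higher and 2 lower (17 and 2 adjusted over the list alone), with CWP1 at 1.29 ± 0.057 and PIR3 at 1.99 ± 0.26. For the cell wall genes camera gave adjusted p = 0.000207, and adjusted p = 0.186 with an estimated correlation.

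Quiescence and starvation markers in the double mutant had 10 of 16 higher and 3 lower (10 and 3 adjusted over the list alone), with GRE1 at 1.10 ± 0.31. For the quiescence markers camera gave adjusted p = 0.00494, and adjusted p = 0.18 with an estimated correlation. Heat shock factor targets had 11 of 22 higher and 2 lower (11 and 2 adjusted over the list alone), with the chaperone gene KAR2 at 0.81 ± 0.23. For the heat shock factor targets camera gave adjusted p = 0.00863, and adjusted p = 0.487 with an estimated correlation. Oxidative phosphorylation had 19 of 37 higher and 1 lower (19 and 1 adjusted over the list alone), with RIP1 of complex III at 0.44 ± 0.011. For oxidative phosphorylation camera gave adjusted p = 0.00723, and adjusted p = 0.487 with an estimated correlation. COS genes had 10 of 12 higher and 1 lower (10 and 2 adjusted over the list alone; camera adjusted p = 0.00253; adjusted p = 0.264 with an estimated correlation), with COS12 at 2.12 ± 0.25, and all 8 helicase genes of Y' elements, which share near-identical sequence, were lower (8 adjusted over the list alone; camera adjusted p = 0.00494; adjusted p = 0.49 with an estimated correlation). Seripauperin genes had 17 of 30 lower and 8 higher (17 and 8 adjusted over the list alone; camera adjusted p = 0.0248; 0.0507 without replicate 2; adjusted p = 0.676 with an estimated correlation), and AAD and vitamin genes 9 of 13 lower and 1 higher (9 and 1 adjusted over the list alone; camera adjusted p = 0.000209; adjusted p = 0.0607 with an estimated correlation), with SNZ3 at -2.31 ± 0.052. The outermost 5 places had 72 of 140 genes lower and 23 higher (72 and 24 adjusted over the list alone; camera adjusted p = 0.000805; adjusted p = 0.487 with an estimated correlation), and places 6 to 10 had 69 of 146 lower and 37 higher (71 and 37 adjusted over the list alone; camera adjusted p = 0.0348; adjusted p = 0.0885 with an estimated correlation). Genes beside centromeres had 58 of 153 higher and 17 lower (57 and 17 adjusted over the list alone), and those named by the rule, SAG1, RER1, CIT2 and YCL001W-A, include genes of the alpha-specific list and of chromosome III. For the centromere list camera gave adjusted p = 0.00494, and adjusted p = 0.18 with an estimated correlation.

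Other remodellers had 13 of 21 lower and 1 higher in the double mutant (13 and 1 adjusted over the list alone), with RSC8 of the RSC complex at -0.60 ± 0.071. For the other remodellers camera gave adjusted p = 0.0203, and adjusted p = 0.264 with an estimated correlation. Ribosome biogenesis had 33 of 118 higher and 6 lower (30 and 6 adjusted over the list alone); the call ended without replicate 2 (0.0507) and without replicate 3 (0.0514), and the direction turned on the arrays with the mutant in Cy5 (0.842). For ribosome biogenesis camera gave adjusted p = 0.0308, and adjusted p = 0.537 with an estimated correlation. Ribosomal protein genes had 54 of 138 lower and 4 higher (52 and 4 adjusted over the list alone), a direction that turned with median centring (0.725) and with the mutant in Cy5 (0.00105). For the ribosomal protein genes camera gave adjusted p = 0.000266, and adjusted p = 0.554 with an estimated correlation. The other 21 lists had camera adjusted p from 0.124 to 0.998. Among them, stress response genes had 17 of 47 higher and 15 lower (17 and 15 adjusted over the list alone; 0.84), with a median of -0.097, a mean of 0.083 and an upward test. Pheromone response genes had 11 of 22 higher and 9 lower (12 and 9 adjusted over the list alone; 0.699), with a median of 0.20, a mean of -0.14 and an upward test. On the arrays with the mutant in Cy5 alone, 13 of the 22 called lists stayed past the threshold in the same direction. The calls ended for Y' helicases (0.959), heat shock factor targets (0.267), oxidative phosphorylation (0.24), seripauperin genes (0.24), the outermost 5 places (0.109), places 6 to 10 (0.0577) and Gcn4 targets (0.0545). Places 6 to 10 also lost the call with the filter on all 18 arrays (0.0652), other remodellers with the mutant in Cy3 alone (0.0832), ribosomal protein genes with arrays not averaged (0.0861), and ribosome biogenesis with arrays not averaged (0.0528) and with the deposited ratios (0.0564).

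Comparing the mutants with each other asks which effects differ between the deletions. Between fun30D and htz1D, EGO4 was higher in fun30D by 3.24 ± 0.13 (SD, n = 3; adjusted p = 4.71e-08), COS10 by 2.98 ± 0.074 and RDS1 by 2.93 ± 0.46, while DAN1, FIT2, FIT3 and FRE5 stood at -2.05 ± 0.25, -1.94 ± 0.12, -1.91 ± 0.11 and -1.67 ± 0.38. Of 47 stress response genes, 36 were higher in fun30D and 3 lower (37 and 3 adjusted over the list alone). For the stress response genes camera gave adjusted p = 5.49e-13, and adjusted p = 0.208 with an estimated correlation. Seripauperin genes had 26 of 30 higher in fun30D and 2 lower (27 and 2 adjusted over the list alone; camera adjusted p = 5.08e-12; adjusted p = 0.208 with an estimated correlation), and genes in places 6 to 10 from chromosome ends 72 of 146 higher and 20 lower (77 and 23 adjusted over the list alone; camera adjusted p = 6.32e-07; adjusted p = 0.00702 with an estimated correlation). The iron regulon had 18 of 29 lower and 3 higher (21 and 3 adjusted over the list alone). For the iron regulon camera gave adjusted p = 4.67e-06, and adjusted p = 0.251 with an estimated correlation. In all, 2704 genes differed, 1333 higher and 1371 lower in fun30D, and 1373 without replicate 1, the count within the later scan batch. At least 1.5-fold, 502 were higher and 217 lower in fun30D, and at least 2-fold, 231 and 36. With the batch as a term 2648 genes differed, and with the mutant in Cy3 alone 1571.

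The double mutant was compared with each single mutant, again beside the chromosome III median of 0.68 of the double mutant. Against fun30D, 2343 genes differed, 1184 higher and 1159 lower, or 2116 without chromosome III and the mating, meiosis, methionine and marker lists. Against htz1D, 2010 differed, 1103 higher and 907 lower, or 1763 without them. At least 1.5-fold, 427 were higher and 180 lower against htz1D, and 308 and 333 against fun30D. MET17 stood at 8.01 ± 0.46 and 8.08 ± 0.33 (SD, n = 3), MF(ALPHA)1 at 6.14 ± 0.15 and 6.71 ± 0.053, LYS2 at -5.22 ± 0.087 and -4.99 ± 0.15, and MFA2 at -2.84 ± 0.19 and -3.18 ± 0.27, against fun30D and htz1D in turn. HSP12 was higher than in fun30D by 4.38 ± 0.44 and HPF1 by 3.82 ± 0.71, and ARG1 was higher than in htz1D by 3.77 ± 0.94. Against htz1D, 42 of 47 stress response genes were higher and 0 lower (43 and 0 adjusted over the list alone; camera adjusted p = 5.47e-23; adjusted p = 0.102 with an estimated correlation), as were 33 of 37 oxidative phosphorylation genes (33 adjusted over the list alone; camera adjusted p = 3.6e-12; adjusted p = 0.102 with an estimated correlation), and ribosome biogenesis had 53 of 118 lower and 4 higher (62 and 4 adjusted over the list alone; camera adjusted p = 1.72e-09; adjusted p = 0.108 with an estimated correlation). Against fun30D, 15 of 18 phosphate genes were lower and 0 higher (15 and 0 adjusted over the list alone). For the phosphate genes camera gave adjusted p = 3.44e-09, and adjusted p = 0.0201 with an estimated correlation. Without replicate 1 the counts were 1093 against fun30D and 1031 against htz1D, with the scan batch as a term 2307 and 1976, and with the mutant in Cy3 alone 1403 and 1174.

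The interaction asks where the double mutant departs from the sum of the single effects on the log2 scale, and it also holds the strain background of the double mutant. In all, 1652 genes departed, 895 above the sum and 757 below it, and at least 1.5-fold, 448 above and 236 below. ARG1, low in both single mutants, stood 4.99 ± 1.26 above the sum (SD, n = 3; adjusted p = 3.58e-06) and HSP12 4.06 ± 0.39 above it. MET17, MF(ALPHA)1 and MF(ALPHA)2 stood at 8.01 ± 0.47, 6.38 ± 0.092 and 5.12 ± 0.54, and LYS2, MFA1, MFA2, STE2 and HO at -4.60 ± 0.11, -3.39 ± 0.50, -3.34 ± 0.32, -2.96 ± 0.51 and -2.78 ± 0.30. Of 47 stress response genes, 40 stood above the sum and 0 below it (41 and 0 adjusted over the list alone), with a median of 1.18 (camera adjusted p = 3.2e-23; adjusted p = 0.117 with an estimated correlation). Oxidative phosphorylation had 33 of 37 above and 0 below (35 and 0 adjusted over the list alone; camera adjusted p = 1.44e-16; adjusted p = 0.117 with an estimated correlation), Gcn4 targets 31 of 54 above and 1 below (33 and 3 adjusted over the list alone; camera adjusted p = 4.35e-11; adjusted p = 0.117 with an estimated correlation), and ribosome biogenesis 43 of 118 below and 2 above (51 and 2 adjusted over the list alone; camera adjusted p = 2.17e-10; adjusted p = 0.124 with an estimated correlation). The Gcn4 targets include MET17, LYS2 and 3 chromosome III genes. Chromosome III had a median of 0.69 above the sum, and 1417 genes departed from it outside chromosome III and the mating, meiosis, methionine and marker lists. Without replicate 1, 695 genes departed from the sum, and 1575 with the scan batch as a term. With the replicate block 2005 genes did. At the preset correlation, the only one run with the block, camera also called the Y' helicases (0.0462), mitochondrial DNA genes (0.0479) and seripauperin genes (0.0451).

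Calls of the single mutants were compared with those of the double mutant, whose strain background cannot be separated from the deletions. Some lists called lower in htz1D were not called lower in the double mutant. Stress response genes went from 38 lower and 2 higher to 15 lower and 17 higher, oxidative phosphorylation from 26 lower and 0 higher to 1 lower and 19 higher, and Gcn4 targets from 32 lower and 5 higher to 6 lower and 29 higher. With an estimated correlation camera called none of these lists in htz1D (adjusted p = 0.239, 0.264 and 0.279 in turn). The same held in the double mutant (adjusted p = 0.956, 0.487 and 0.356). Of 6105 genes other than the deleted ones, 894 were higher and 977 lower in both htz1D and the double mutant, against 446.6 and 471.1 for independent lists, while 118 and 222 went opposite ways (471.4 and 446.4). Of the 179 genes lower in htz1D by at least 2-fold, 120 were lower and 21 higher in the double mutant, with medians of -1.41 and -0.52. The correlation of the ratios across genes, which are not independent replicates, was 0.407, and 0.402 in simulations of unchanged strains against the same WT cultures. The simulated value follows from the 41.8% of variance set as shared, so the correlations decide nothing. With fun30D the correlation was 0.174 for the double mutant (0.42 simulated) and 0.105 for htz1D (0.405 simulated). Between htz1D and the double mutant the covariance was 0.0741 against 0.00237 in those simulations. It was 0.0712 between replicates of different numbers, which share no WT culture. For fun30D and the double mutant, 394 genes were higher and 316 lower in both (209.1 and 217.3 for independent lists), and 172 and 133 went opposite ways (220.7 and 205.9), with a covariance of 0.0153 against 0.00245 simulated and 0.0135 between different numbers. Of the 5 genes higher in fun30D by at least 2-fold, 3 were higher and 0 lower by limma in the double mutant, and of the 9 lower, 5 were higher and 1 lower. For fun30D and htz1D, 307 were higher and 276 lower in both (216.2 and 212.7). The opposite-direction counts were 259 higher in fun30D and lower in htz1D (216 for independent lists) and 135 the other way (212.9). This pair had ratios with a covariance of 0.00893 against 0.00234 simulated and 0.00436 between different numbers, where it ranged from -0.00688 to 0.0125.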

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

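The tests on chromosome III, the mating genes and the marker genes were chosen only after the result was seen. The results below differ between strains by the interaction term, the double mutant minus the sum of the single mutants. It would test whether deleting FUN30 acts differently with HTZ1 present or deleted if the strains differed in nothing else. The double mutant also differed in mating-type genes, MET17, LYS2 and chromosome III, so the term cannot separate such an effect from strain background. The term called 1652 genes.

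Highest above the sum of the single effects were MET17 at 8.01, MF(ALPHA)1 at 6.38, MF(ALPHA)2 at 5.12, ARG1 at 4.99 and HSP12 at 4.06. Lowest were LYS2 at -4.60, MFA1 at -3.39, MFA2 at -3.34, STE2 at -2.96 and HO at -2.78. Of the list medians, alpha-specific genes stood at 4.55, stress response genes at 1.18, quiescence and starvation markers at 0.784, oxidative phosphorylation at 0.668, Gcn4 targets at 0.558, mating cassette genes at 0.466 and COS genes at 0.159. Below the sum were a-specific genes at -2.69, pheromone response genes at -0.474, the iron regulon at -0.455, ribosome biogenesis genes at -0.244, AAD and vitamin genes at -0.226, M/G1 and daughter-specific genes at -0.203 and the proteasome at -0.136. With an estimated correlation the camera adjusted p of these 14 lists lay between 0.0562 and 0.646, past the threshold for no list. The COS call ended without replicate 2 (adjusted p = 0.0505), without replicate 3 (0.0791), with scaling between arrays (0.304), with offset 10 (0.0523), with the scan batch as a term (0.051), with arrays not averaged (0.0535) and with the mutant in Cy3 (0.0657) or Cy5 alone (0.0835). The proteasome call ended without replicate 1 (0.139), without replicate 2 (0.0929), with median centring (0.145), with offset 10 (0.0523), with arrays not averaged (0.0845), with the filter on all 18 arrays (0.0517) and with the mutant in Cy5 alone (0.846). The AAD and vitamin call ended with the filter on all 18 arrays (0.149), with median centring (0.0685) and with the mutant in Cy5 alone (0.0835), and the M/G1 call with the mutant in Cy5 alone (0.0772).

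The double mutant had higher alpha-specific RNA, lower a-specific RNA (from STE2 at -2.79 to ASG7 at -0.70, the latter chosen after its value was seen), high MET17, low LYS2 and higher RNA along chromosome III. As the source of the rise along chromosome III, loss of silencing at the chromosome ends is argued against, since the lowest median among the 4 middle runs was 0.659. The runs left out the mating lists, so this value does not bear on silencing of the mating cassettes or on the mating genes. RNA of WT or single-mutant cells mixed in is argued against, since LYS2 kept at most 2.21% of the WT signal, under the share that STE2 kept. A candidate explanation is an extra copy of chromosome III in cells with other mating-type genes and another marker genotype. The lower of the medians of both arms was 0.659, but this restates the rise that prompted the explanation and is no test of it. The last 2 runs of genes at the right end stood at 0.43 and 0.21, which an even gain does not give by itself, and at -0.17 and -0.43 in htz1D. Genes known to be transcribed in haploid cells also fell, such as STE4 at -2.17 and STE18 at -2.29, which another mating type alone leaves unexplained. Cells with mating-type genes of both kinds were not tested as a source, and HMRA1 stood at -0.35 beside the higher alpha-specific RNA. The fall thus does not argue against an extra copy of chromosome III. The strain background cannot be told apart from the deletions as the source of the 3097 genes changed outside chromosome III and the mating, meiosis, methionine and marker lists, because all 3 double-mutant samples carry both. A biological interaction of FUN30 and HTZ1 stays open for the same reason.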

How the results depend on the processing

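The scan batch term and the counts without chromosome III and lists were chosen only after the results were seen. Of 131 list calls, 119 were lost with an estimated correlation. Over all settings, list calls were the same in 2171 comparisons, lost in 228 and turned in 5. For 510 named gene ratios, 8510 comparisons with other settings kept direction and side of the threshold, 623 lost the call and 16 turned. Dim signal over background limits the 149 genes left out and the low side of FUN30, HTZ1 and LYS2. The brightest-probe alternative was not run, since each gene had 1 probe. Except where said, the cause was not tested.

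Scaling between arrays gave 2529 genes in fun30D, and the 6 WT arrays as a group on the deposited ratio scale, which changes 2 choices at once, 904 (the deposited ratios alone gave 1491). With the mutant in Cy3 alone, 1403 genes differed between the double mutant and fun30D, 1174 between the double mutant and htz1D, and 1571 between fun30D and htz1D, with fewer arrays. A minimum of 1.5-fold, stricter by construction, left 94 in fun30D, 634 in htz1D, 580 in the double mutant, 641 and 607 for the double mutant against fun30D and htz1D, 719 for fun30D against htz1D and 684 for the interaction. Leaving out 1 replicate, which leaves fewer samples, gave 268 to 1132 in fun30D, 1093 to 1814 and 1031 to 1566 for the double mutant against fun30D and htz1D, 1373 to 2208 for fun30D against htz1D and 695 to 1270 for the interaction. The lowest of each came without replicate 1.

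With the replicate block, 1579 genes were called in fun30D, 3372 in htz1D and 3344 in the double mutant, 2791 and 2445 for the double mutant against fun30D and htz1D, 3173 for fun30D against htz1D and 2005 for the interaction. COB (adjusted p = 0.0519) and FLO5 (0.0529) lost their calls. Lists gained with it were phosphate genes in fun30D (0.0469) and Y' helicases (0.0462), mitochondrial DNA genes (0.0479) and seripauperin genes (0.0451) in the interaction. These gained calls rest on the preset correlation, since no estimated correlation was run with the block. As a fixed term the block ended the call of neighbours between fun30D and htz1D (0.0588).

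With the mutant in Cy3 alone, ratios turned for HTB2 in fun30D (0.00115), for RPS14A (-0.275), PRE9 (0.0919) and RPN8 (0.108) in the double mutant, and for HHF1 (-0.373), PGK1 (-0.638), HTA1 (-0.377), RSC8 (0.0349), ENO2 (-0.905) and ARP5 (0.115) in htz1D. With the mutant in Cy5 alone they turned for HHF1 (0.349), GAL3 (-0.0214), RPL26B (0.537) and RPS7B (0.15) in fun30D, CRH1 (-0.0351) in the double mutant and FUN30 (-0.189) in htz1D. Ribosomal protein genes turned in fun30D with the mutant in Cy5 (camera adjusted p = 2.88e-11), in the double mutant with that choice (0.00105) and with median centring (0.725), and between the double mutant and htz1D with median centring (0.478). Ribosome biogenesis genes turned in the double mutant with the mutant in Cy5 (0.842).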

Other observations

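The tests on leftover HTZ1 signal and the process terms were chosen only after the results were seen. Gene annotations on the array gave 67 process terms with at least 10 genes, of which camera called 6 in fun30D, 5 in htz1D and 5 in the double mutant. In fun30D, genes of proton transport coupled to ATP synthesis had 12 of 20 lower and 1 higher (camera adjusted p = 0.000743, and adjusted p = 0.413 with an estimated correlation). The same term had 10 of 20 lower and 0 higher by limma in htz1D (0.048, and adjusted p = 0.736 with an estimated correlation) and 13 higher and 1 lower in the double mutant (0.0271, and adjusted p = 0.738 with an estimated correlation). In htz1D, genes that process the 20S precursor of ribosomal RNA had 13 of 15 higher and 0 lower by limma (camera adjusted p = 0.00107, and adjusted p = 0.589 with an estimated correlation). In the double mutant, thiamin synthesis had 7 of 11 lower and 1 higher, with a median of -0.62 (camera adjusted p = 0.0386, and adjusted p = 0.511 with an estimated correlation). On chromosome IX in htz1D, 89 of 210 genes were lower and 40 higher (camera adjusted p = 0.0318, and 0.0399 with an estimated correlation).

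Dye swaps of fun30D correlated across genes, which are not independent replicates, by 0.143, 0.22 and -0.134 in the 3 replicates, against 0.672, 0.482 and 0.616 in htz1D and 0.738, 0.704 and 0.64 in the double mutant.

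In htz1D, genes in the outermost 10 places of chromosome ends were lower, 158 of 286 lower and 44 higher. Signal shared within families marked by gene symbol is argued against as the whole cause. Without their members camera gave p = 3.92e-06 over 212 genes (0.00635 with an estimated correlation). Similar copies under other symbols may remain among these 212, so shared signal as such stays open. Dim probes are argued against as the whole cause by the brighter 143 genes (p = 0.00136, and 0.177 with an estimated correlation), but the median went from -0.21 over all genes to -0.11 in these, so dim probes may carry part of it. A role of H2A.Z near chromosome ends may be a candidate explanation, and it was not tested apart from these.

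HTZ1 signal was left in samples without the gene. WT RNA as the only source is argued against in replicates 2 and 3 of the double mutant, since HTZ1 kept at least 5.69% of WT there while FUN30 and LYS2 kept less. In replicate 1 HTZ1 kept 1.45% and FUN30 and LYS2 each kept 1.96%, so WT RNA stays open there. In htz1D, where HTZ1 kept up to 3.83%, WT RNA cannot be told apart from other sources, since no other gene is missing. Binding of other transcripts could not be decided either, with a 4.06-fold range of the share in the double mutant.

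Other arrangements of the samples were too few for a share under 0.05. For fun30D, htz1D, the double mutant and the interaction, the others were made by turning the sign of the ratios of 1 replicate. There 1 of 4 arrangements, the real one, gave as many genes, 1561, 3358, 3340 and 1652, and the highest other gave 0 by limma. Turning a replicate that goes with the others shrinks the mean and widens the spread. These low counts were therefore built in and say nothing about chance. Between mutants 1 of 10 splits, the real one, gave as many, with 2343 (highest other 0) for the double mutant against fun30D, 2010 (highest other 1) against htz1D and 2704 (highest other 0) for fun30D against htz1D. Where strains differ, the other splits put replicates of both strains in each group, which shrinks the difference and widens the spread. Their low counts say nothing about chance either.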
